A study of Gallus gallus with 2 samples.

How the data were processed

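Gene expression was measured in the chicken B cell line DT40, an established line derived from the bursa of Fabricius, in wild-type cells and in cells deficient for PTIP, the product of PAXIP1, in which every allele was disrupted according to the labels. There was 1 sample per genotype, so 2 arrays in all, and neither culture, RNA preparation nor hybridisation was replicated. Per the labels' protocols, both cultures were kept at the same temperature, total RNA was extracted with a commercial reagent, and biotin-labelled cRNA was made with the one-cycle 3' amplification chemistry and hybridised to the Affymetrix chicken genome array, which carries a single label per array.

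The deposited values are linear signal intensities, 1 per probe set and array, for 38535 probe sets. The authors processed the scans with GCOS, the scanner vendor's software, per the submitters' processing notes; its version and algorithm are not given in the sources used here. In the deposited intensity values, the mean of the values between percentiles 2 and 98 was 499.9 in both arrays, so each array had already been scaled to a common target. Such scaling assumes that the average transcript level was equal in both cell populations, and a difference in the amount of RNA per cell cannot be seen in these values. Detection calls were not used here.

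No further scaling was applied in the main analysis, and the log2 ratio of each probe set was taken as PTIP deficient minus wild-type. The 96 control probe sets of the manufacturer were left out, which left 38439. A probe set was called measured in an array where its signal reached a floor of 31.0, percentile 40 of all non-control values of both arrays together. In the main analysis a ratio was formed only where both signals reached the floor. Where 1 signal lay under it, the ratio was counted as a bound ("at least") of the bright signal against the floor, and where both did, no ratio is given. The floor is a rank and not a test against background: the 57 probe sets for reporter and marker sequences reached 131.5 outside 1 bright signal. After seeing the data, the fold difference of a named gene with 1 signal under 131.5 was therefore given as a bound of the bright signal against 131.5, while counts, log2 ratios and list medians use the floor of 31.0. Genes came from the platform annotation: 27178 probe sets had 1 gene symbol, 177 had several and were not named, and 11180 had none. Of the 27178, 26863 matched a gene of the GRCg7b RefSeq annotation by Entrez identifier, and the match altered 0 symbols. The build used for the array design is not given in the sources used here. Only chromosome, gene order, gene symbols and their synonyms were taken from that annotation. For each of 13009 genes, the probe set with the highest mean log2 signal was used, and 9165 genes were measured in both arrays.

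With 1 array per genotype no test between genotypes exists, and no p-value, standard error or count of significant genes is given. A difference is described by its size, with 2-fold as the bar. The only repeat measurement is that of different probe sets for the same gene, which covers probe error. It covers neither a hybridisation difference shared by a whole array nor the spread between cultures or clones. It was summarised as the SD of the difference between the log2 ratios of the 2 brightest measured probe sets of a gene. The precision of the values is limited by the number of arrays.

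A set of 28 gene lists was fixed before the data were examined, together with the floor, the alternatives and the rule for naming genes. They covered H3K4 methyltransferase complexes, DNA repair and checkpoint pathways, B cell receptor and identity genes, germinal centre regulators, MHC class II, replication, mitosis, p53 targets, apoptosis, ribosome, proteasome, glycolysis, oxidative phosphorylation, cholesterol synthesis, stress and interferon responses, MYC targets, HOX genes, housekeeping genes, and markers of T cells, macrophages and granulocytes, erythroid cells and thrombocytes, and mesenchymal and epithelial cells. Of 824 listed symbols, 677 matched a gene on the array directly or through a unique RefSeq synonym, and members are named as RefSeq names them (JCHAIN was listed under its older symbol IGJ, and XIAP, BLNK and WDR5 are BIRC8, SH2D6 and WDR5B there). For each list, the median log2 ratio of its measured members was set against 10000 random lists of the same size, matched on mean signal in 10 bins, and a list was said to stand apart where its median fell outside the central 95% of the random medians. With 28 lists, 1.4 would do so by chance if lists were independent. The percentile describes these 2 arrays and is not a test across cultures. The same procedure was applied to 31 chromosomes with at least 20 measured genes.

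Genes named in the text are PAXIP1, the 10 highest and 10 lowest ratios among genes measured in both arrays, the 5 largest bounds each way, and up to 3 measured members of each list with the largest absolute ratio. For the 20 highest and lowest, all measured probe sets of a gene had to have the same sign, and clone-derived symbols were left out. For a bound, no probe set of the gene could reach the floor in the other array. That reading of the rule, the pairing of the 2 brightest probe sets, the loess span and the matching of listed symbols through synonyms were settled after the values had been seen. A gene named outside this rule is marked as chosen after its values were seen.

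The list procedure was tested on simulated data in which ratios were shuffled within signal bins over the 9165 genes. Among 100 simulated lists of 35 genes, a shift of 0.2 on the log2 scale was found in 70% and a shift of 0.3 in 96%; among lists of 10 genes a shift of 0.3 was found in 46%. Without a shift, 1% of the lists of 35 genes were called higher and 1% lower, and 1% and 3% of the lists of 10 genes. Shuffling removes correlation between genes, so these rates do not carry over to lists of genes that vary together. For the 2-fold counts, the wild-type array was given random error with the SD of a single probe set, 0.36, at every signal level. The changed probe sets were drawn only from those well above the floor in wild-type. Of 100 changed by 1.5 on the log2 scale 94 were recovered, and of 22144 measured unchanged ones 93 passed 2-fold. In the real data the spread between probe sets was larger with lower floors, so these rates do not apply near the floor.

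Alternatives were median centring, quantile normalization, loess on the mean level with a span of 0.3, floors at percentiles 20 and 60 and no floor, thresholds of 1.5-fold and 3-fold, the mean of all probe sets per gene, leaving out probe sets whose name marks possible cross-hybridisation (suffixes _s_at and _x_at), and random lists not matched on signal. For named genes, the mean of all probe sets and the value without _s_at and _x_at probe sets could rest on signals under the floor. An alternative without the genes of chromosomes 9, 20, Z and W and one with the floor at the highest reporter signal were added after seeing the data. Of the explanations weighed in the closing observations, the tests and their thresholds were also set after the patterns had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.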

Results

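DT40 cells with and without PTIP were profiled on 1 array each to find which transcripts differ in its absence; PTIP is a BRCT-domain protein of the DNA damage response that is also a subunit of a histone H3K4 methyltransferase complex. Of 38439 probe sets, 22912 (59.6%) reached the signal floor of 31.0 in the wild-type array and 23215 (60.4%) in the PTIP deficient array. The ratio of the 3' to the 5' probe set of actin, a measure of RNA integrity, was 1.20 in wild-type and 1.09 in PTIP deficient cells, and that of GAPDH was 1.06 and 0.98. The log2 signals of the 20310 probe sets measured in both arrays correlated across probe sets with a Pearson r of 0.96; probe sets are not independent replicates. None of the differences below has a replicate check.

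PAXIP1 (Entrez gene 420441, chromosome 2), the disrupted gene, had a signal of 1045 in wild-type and 593 in PTIP deficient cells with its only measured probe set, a 1.76-fold lower signal (log2 ratio -0.82) or 56.8% of wild-type. The 2 other probe sets of PAXIP1 were under the floor in both arrays, at 4.34 and 19.7 in wild-type and at 8.66 and 6.65 in PTIP deficient cells. The position of these probe sets relative to the targeted exons is not given in the sources used here, so these values do not show whether the alleles were disrupted. That probe set is of the _s_at kind, which can detect related sequences.

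JCHAIN, which encodes the chain that joins polymeric immunoglobulins, had a signal of 68.5 in PTIP deficient cells against 11947 in wild-type cells and was at least 90.8-fold lower. CD72, a B cell co-receptor, was at least 22.4-fold lower (87.4 against 2951), and LITAF was 27.6-fold lower (226 against 6249). The measured probe sets of CD72 ranged from -5.08 to -3.10 on the log2 scale and those of LITAF from -5.51 to -4.79. Of the 20 genes with the highest and lowest ratios, 19 had a signal in 1 array under 131.5, the highest signal of the reporter probe sets, so that their differences are given as bounds against that signal and their order is not settled. Also among the 10 lowest ratios were PPP1R14C at least 36.3-fold lower, NEUROD6 at least 25.6-fold, DACT2 at least 14.8-fold, PINLYP at least 11.6-fold, RBM38 at least 13.2-fold, the fatty acid elongase ELOVL7 at least 14.3-fold and the pseudokinase TRIB2 at least 14.5-fold. The second measured probe set of RBM38 gave a log2 ratio of only -0.68, against -5.14 for the brightest, and that of TRIB2 gave -3.30 against -4.80. Of the genes under the floor in PTIP deficient cells, TM6SF1 was at least 16.6-fold lower, MYO10, an unconventional myosin, at least 11.8-fold, MCOLN2 at least 10.8-fold, CA3B at least 10.4-fold and BLVRA, a biliverdin reductase, at least 9.75-fold.

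In the other direction, the galectin genes LGALS1A and LGALS1B were at least 20.6-fold and 6.0-fold higher in PTIP deficient cells, LGALS1A having a signal of 2703 against 43.7. PPDPF was at least 26.6-fold higher, CTBP2, a transcriptional corepressor, at least 14.3-fold, CPEB1, an mRNA-binding protein, at least 8.65-fold, and PROM1 at least 6.46-fold. The actin-bundling plastins LCP1 and PLS3 were at least 13.6-fold and 12.6-fold higher, and both measured probe sets of each gene gave similar ratios, from 4.20 to 4.41 on the log2 scale for LCP1 and from 3.61 to 3.79 for PLS3. KLF13, a Krüppel-like transcription factor, was at least 10.9-fold higher, with log2 ratios of 2.07 to 3.96 over 3 probe sets. TSPAN12 was at least 7.82-fold higher by 1 of its 2 probe sets, and the other, not measured in both arrays, had the opposite sign, and the mean of both gave a log2 ratio of 0.99. Among genes under the floor in wild-type cells, the aldo-keto reductase AKR1B10 was at least 38.5-fold higher (signal 5063), SYPL1 at least 12.1-fold, PITPNC1L at least 11.6-fold, the proteoglycan LUM at least 7.75-fold and CLEC19A at least 6.09-fold.

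**Figure D1:**
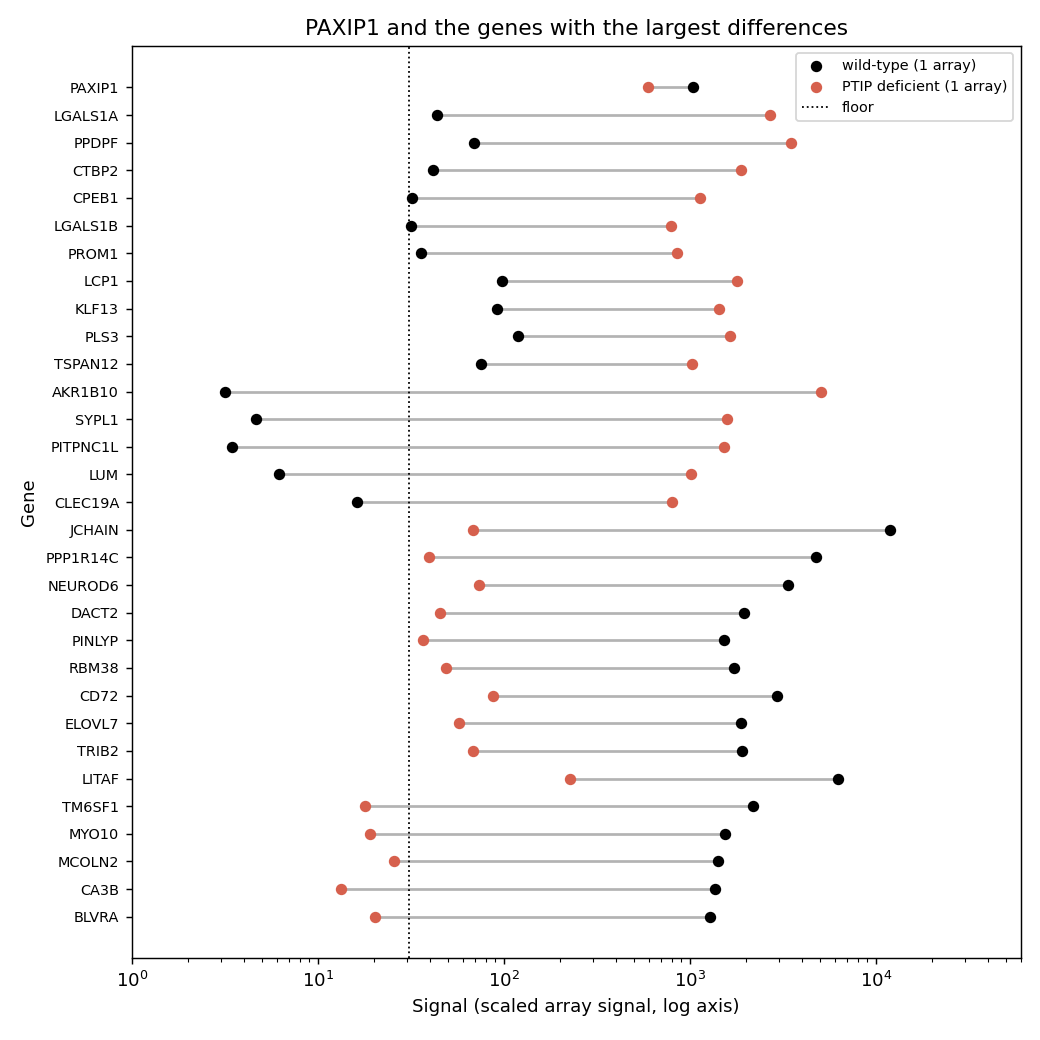
Signal (scaled array signal, log axis) of PAXIP1 and of the genes with the largest ratios and bounds in the wild-type (black) and PTIP deficient (red) arrays, 1 array each; the dotted line is the floor of 31.0. PAXIP1 differs by 1.76-fold, whereas JCHAIN lies at 11947 and 68.5 and LGALS1A at 43.7 and 2703.

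Over all probe sets measured in both arrays, 994 were at least 2-fold higher and 952 at least 2-fold lower in PTIP deficient cells, together 9.58% of 20310. By gene, 461 were higher and 409 lower among 9165. A further 553 probe sets measured only in PTIP deficient cells and 554 measured only in wild-type cells had a bound of at least 2-fold. The log2 ratios of the 2 brightest probe sets of a gene differed with an SD of 0.50 over 4284 genes, or 0.36 per probe set. Of 358 genes whose brightest probe set was at least 2-fold apart, the second had the same sign in 315 (88.0%, close to 50% being given by chance) and was itself at least 2-fold apart in the same direction in 194 (54.2%). The counts depend on the floor: with it at percentile 60, 489 probe sets were higher and 446 lower, and with it at the highest reporter signal, 385 and 342.

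B cell genes were lower as a group in PTIP deficient cells. Of 29 measured genes of B cell receptor signalling and B cell identity, 8 were at least 2-fold lower, 0 at least 2-fold higher and 21 within 2-fold. Among the 8 was FCRL4, chosen after its values were seen, with signals of 100 and 39.8, under 131.5 in both arrays. The median log2 ratio of the list was -0.20, at percentile 0.57 of matched random lists. Besides JCHAIN, the immunoglobulin light chain gene IGLL1 was 8.28-fold lower (3619 against 29961), with log2 ratios from -4.23 to -0.30 over its 6 measured probe sets, and POU2AF1, a coactivator of immunoglobulin promoters, was 4.21-fold lower (1943 against 8186). The brightest IGLL1 probe set is of a kind that can detect related sequences. T cell markers were higher in the same array (median 0.65 over 8 genes, most of them with a wild-type signal under 131.5). The B cell list no longer stood apart with a floor at percentile 60 (median -0.15 over 27 genes, percentile 3.27) or without _s_at and _x_at probe sets (median -0.14 over 23 genes, percentile 6.16).

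Among 18 measured regulators of germinal centre and plasma cells, 4 were at least 2-fold lower and 3 at least 2-fold higher, and the median of 0.09 was at percentile 70.2. IRF4, a transcription factor of B cell activation and plasma cell differentiation, was 16.8-fold lower, at 256 against 4312. ID3 and ID2, inhibitors of E-protein transcription factors, were at least 4.28-fold and 4.56-fold higher, respectively, ID3 against the highest reporter signal. In the MHC class II list, 2 of 9 measured genes were at least 2-fold lower and the median was -0.41 (percentile 1.35). The protease gene CTSS was 4.21-fold lower while RFX5, at 102 in wild-type and so under the highest reporter signal, was at least 1.46-fold higher. BLB1, an MHC class II beta chain gene and the other of the 2, was measured with 1 of its 5 probe sets, at 112 and 44.1, both under the highest reporter signal, and its log2 ratio was -0.26 with the mean of all probe sets. Without _s_at and _x_at probe sets the median was again -0.41, now over 7 genes, and its percentile 3.25.

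Homologous recombination genes had lower signals in PTIP deficient cells by a modest amount. Of 35 measured genes, 24 had a log2 ratio below 0, 1 was at least 2-fold lower and 0 at least 2-fold higher. The median was -0.32 (0.80-fold), at percentile 0.02 of matched random lists. RAD54L, a recombination motor protein gene, was 2.05-fold lower, BRCA1 1.83-fold and BRCA2 1.81-fold lower. For BRCA1 this is the brightest of 3 measured probe sets, whose log2 ratios ranged from -0.87 to -0.00019. Of the 11 genes above 0, NBN was 1.64-fold and MRE11 1.56-fold higher, both chosen after their values were seen. The replication and mitosis lists were lower too, at medians of -0.37 and -0.23, and random lists were matched on signal only. A shift particular to recombination is therefore not shown. The base excision, mismatch and nucleotide excision repair genes also stood apart, with a median of -0.31 at percentile 0.19 over 25 genes, 15 of them below 0. UNG, the uracil-DNA glycosylase, was 3.12-fold lower (2742 against 8549), OGG1 was 2.11-fold lower, and NEIL1 had a log2 ratio of 0.84. Without _s_at and _x_at probe sets this second list had a median of -0.17 over 16 genes, at percentile 7.54.

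The other repair lists did not stand apart with the settings used throughout. Non-homologous end joining had a median of 0.07 (percentile 63.2, 12 genes), with 0 of 12 at least 2-fold apart; the log2 ratio was 0.71 for LIG4, -0.44 for PRKDC and 0.38 for XRCC4. The 53BP1 and checkpoint list had a median of -0.10 (percentile 9.91, 25 genes) and 0 genes at least 2-fold apart, with log2 ratios of 0.91 for UIMC1, -0.90 for CHEK2 and -0.58 for BRCC3. The Fanconi anaemia list had a median of -0.10 (percentile 20.1, 15 genes), with -0.61 for FANCL, 0.44 for FAN1 and -0.37 for FANCB. With the mean of all probe sets FAN1 was at 1.20, past 2-fold, but that mean took in a probe set not measured in both arrays. The 2 measured ones gave 0.44 and 0.74. Translesion synthesis genes had a median of -0.19 (percentile 5.54, 14 genes); the primase-polymerase PRIMPOL was at least 1.94-fold lower and POLH, the polymerase that bypasses ultraviolet lesions, 2.10-fold lower, while REV1 had a log2 ratio of -0.57. POLH was at -0.94, under 2-fold, without _s_at and _x_at probe sets. This list did stand apart as lower under 5 alternatives, at percentiles from 0.89 to 2.49.

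None of the 13 H3K4 methyltransferase subunits measured in both arrays, PAXIP1 included, was at least 2-fold apart. Over these 13 genes the median was -0.17 (percentile 5.93), and 11 of the 13 were below 0. BOD1L1 had a log2 ratio of -0.57, with measured probe sets of opposite sign, and NCOA6 had signals of 85.5 and 122, under 131.5 in both arrays. Of the methyltransferase genes of the PTIP complex, chosen after their values were seen, KMT2C had a log2 ratio of -0.22, with measured probe sets of both signs, and KMT2D had signals of 108 and 29.8, both under the highest reporter signal. Of the HOX and MEIS genes, 17 of 29 on the array were under the floor in both arrays. The 7 measured in both had a median of -0.01 (percentile 43.0); HOXA4 was at least 2.39-fold higher, and the signals of HOXB7 (90.0 and 46.4) and HOXB5 (42.0 and 32.1) were under 131.5 in both arrays.

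Replication and mitosis genes were lower in PTIP deficient cells. Of 34 measured DNA replication genes, 28 were below 0, 3 were at least 2-fold lower and 0 at least 2-fold higher, and the median of -0.37 (0.77-fold) was below all 10000 random medians. ORC1, the largest subunit of the origin recognition complex, was 2.92-fold lower, the clamp loader subunit RFC3 2.48-fold and the licensing factor CDT1 2.12-fold lower, CDT1 being at -0.94 with the mean of all probe sets. Mitosis and spindle genes had a median of -0.23 (percentile 0.02), 25 of 33 being below 0 and 0 at least 2-fold apart; the log2 ratio was -0.80 for BUB3 and -0.78 for SMC2, and CENPF had signals of 91.4 and 46.3, under 131.5 in both arrays; its log2 ratio of -0.98 was -1.01 under loess. Among 19 cell cycle inhibitors and p53 targets, the antiproliferative gene BTG2 was 3.34-fold higher, the stress-inducible GADD45A 2.82-fold higher and GADD45G at least 2.73-fold lower, and the median was 0.17 (percentile 89.2). Apoptosis regulators had a median of -0.04 (percentile 28.9, 21 genes) and 0 genes at least 2-fold apart. The log2 ratio was -0.75 for BCL2L1 and 0.73 for CASP8. BIRC8 (the gene listed as XIAP), at 113 in PTIP deficient cells and so under 131.5, was at least 1.51-fold lower. The 3 measured probe sets of BCL2L1 ranged from -1.19 to -0.03.

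Several lists of highly expressed genes had slightly higher signals in the PTIP deficient array. Transcripts added to each hybridisation as controls were higher there too, at a median log2 ratio of 0.30 with 27 of 27 probe sets higher. The 36 labelling control probe sets had a median of 0.08. A property of the array and one of the cells therefore cannot be told apart for shifts of this size. Ribosomal protein genes had a median of 0.16 (1.11-fold, percentile 99.8), 56 of 60 lying above 0, but under quantile normalization their median was -0.00036 and the direction was lost (percentile 38.5). RPL31 and RPS3 were 1.24-fold and 1.23-fold higher, whereas RPS13 gave log2 ratios from -0.53 to 1.71 over its probe sets, the highest from signals under 131.5 in both arrays. Oxidative phosphorylation genes had a median of 0.16 (percentile 99.5), 39 of 47 above 0; UQCRB was 2.11-fold higher, and the log2 ratio was 0.49 for NDUFAB1 and -0.56 for COX5A. For UQCRB the log2 ratio was 0.85 with the mean of all probe sets and 0.65 without _s_at and _x_at probe sets, both under 2-fold. Without those probe sets the list was at percentile 92.6, with a median of 0.12 over 40 genes. Glycolysis genes had a median of 0.19 at percentile 97.7, just outside the range, and were inside it under 9 of the alternatives, 87.2 being the lowest percentile. The enolase ENO2 was at least 2.79-fold higher and the lactate transporter SLC16A3 at least 1.73-fold lower, and PFKM had signals of only 37.0 and 84.0. With the mean of all probe sets the log2 ratio was -0.26 for SLC16A3 and 0.63 for PFKM, neither of them 2-fold. Proteasome genes had a median of 0.14 (percentile 92.9, 26 genes), and the largest ratios belonged to PSMD2 (2.13-fold) and PSMD1 (1.68-fold) on chromosome 9 and PSMA7 (1.48-fold) on chromosome 20.

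The remaining metabolic and stress lists did not stand apart. Cholesterol synthesis genes had a median of -0.02 (percentile 32.9, 20 genes), with HSD17B7 2.14-fold and PMVK 2.01-fold higher (PMVK was under 2-fold with each of the 3 other scalings, at log2 ratios from 0.98 to 0.99) and a log2 ratio of -0.80 for LBR, whose probe sets disagreed in sign. The unfolded protein and heat shock list had a median of 0.03 (percentile 45.2, 26 genes) and 0 genes at least 2-fold apart; the log2 ratio was -0.71 for HSPH1, -0.60 for DNAJB9 and -0.51 for ASNS. With the mean of all probe sets HSPH1 was at -1.48, past 2-fold, but that mean took in a probe set not measured in both arrays. Interferon response genes were mostly under the floor, 13 of 23 in both arrays, and the 9 measured had a median of -0.06 (percentile 31.2); the 3 with the largest absolute ratios, PARP9, PARP12 and TRIM25, had signals under 131.5 in both arrays. IRF1, a transcription factor of the interferon response that was chosen after its values were seen, was measured only in wild-type cells and at least 2.17-fold lower in PTIP deficient cells (29.3 against 285). MYC and nucleolar targets had a median of 0.10 (percentile 78.5, 24 genes), with log2 ratios of -0.49 for EIF4E, 0.46 for NOP56 and 0.46 for TFRC with the brightest probe sets. Over all measured probe sets the log2 ratios ranged from -1.51 to -0.49 for EIF4E and from 0.46 to 1.99 for NOP56. Housekeeping genes had a median of 0.17 (percentile 92.9, 12 genes), 11 of them above 0; B2M was near the floor, with signals of 32.0 and 83.1.

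Markers of other cell types were mostly dim in both arrays. T cell markers stood apart, with a median of 0.65 (percentile 99.6) over the 8 measured of 16 on the array, of which 3 were at least 2-fold higher, 0 at least 2-fold lower and 2 below 0. The co-receptor genes CD8A and CD8BP were at least 4.28-fold and 1.44-fold higher in PTIP deficient cells and CD5 at least 2.30-fold higher, at signals of 563, 189 and 303. The other 5, chosen after their values were seen, were CD3D (1.80-fold higher), CD247 (1.37-fold higher) and, under 131.5 in both arrays, ZAP70, CD3E and BCL11B, with log2 ratios of -0.24, -0.03 and 0.04. GATA3 and THEMIS were measured only in wild-type cells and ICOS and IL7R only in PTIP deficient cells, all 4 at signals under 131.5. With the floor at percentile 60 or at the highest reporter signal fewer than 5 T cell markers were measured, so the list has no value there. Macrophage and granulocyte markers had a median of 0.10 (percentile 63.4, 8 genes), with the oxidase subunit CYBB at least 1.71-fold lower and SPI1, also a B cell list member, 2.08-fold lower; TLR2A had a log2 ratio of -0.75. Erythroid and thrombocyte markers had a median of 0.40 (percentile 91.6, 7 genes), the log2 ratio being -0.64 for ALAS1. The signals of HBE (56.4 and 104) and THBS1 (32.5 and 56.3) were under 131.5 in both arrays. Mesenchymal and epithelial markers had a median of 0.33 (percentile 92.9, 10 genes). In that list VIM, the intermediate filament gene vimentin, was 3.03-fold higher (12190 against 4028) and COL1A1 at least 1.56-fold higher at a signal of 206, and KRT24 had signals of 51 and 92.1, under 131.5 in both arrays.

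**Figure D2:**
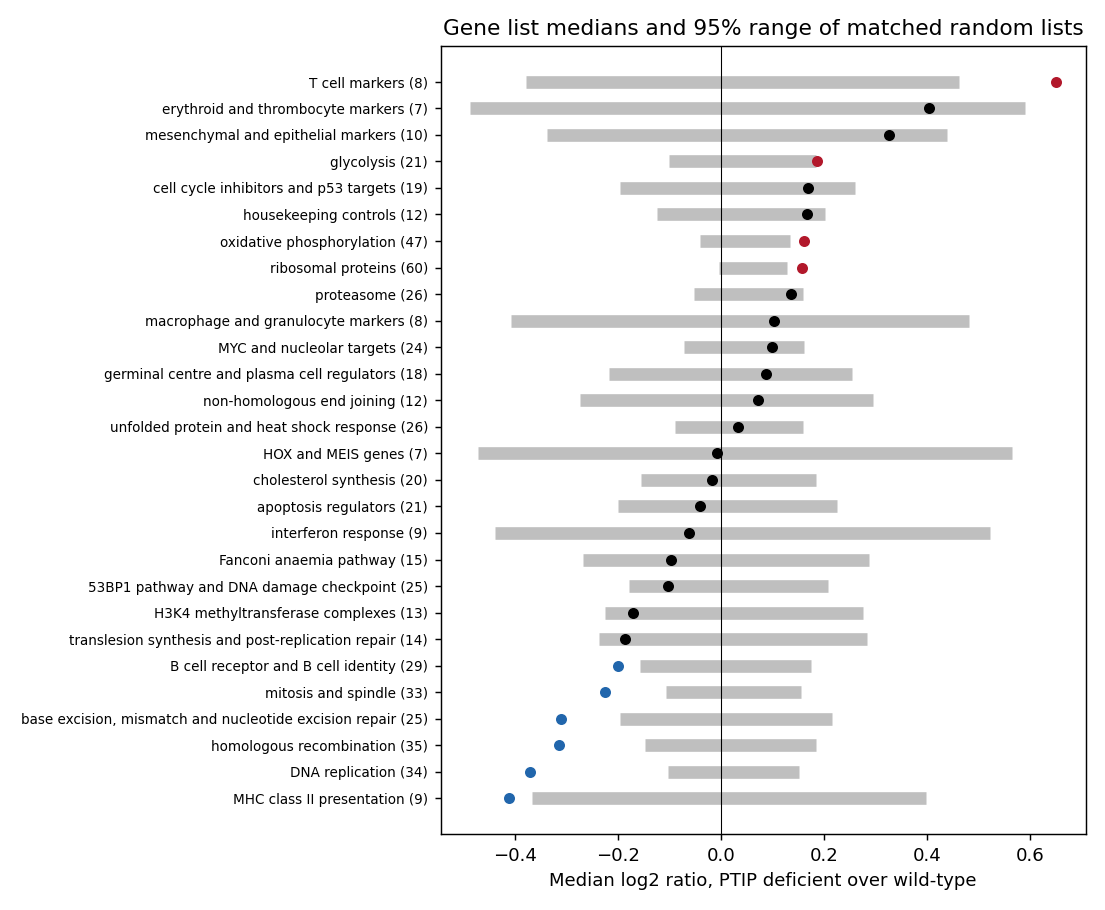
Median log2 ratio (PTIP deficient over wild-type, 1 array each) of each gene list, with its number of measured genes in parentheses; grey bars span the central 95% of 10000 random lists matched on signal, and red and blue points lie above and below them. DNA replication (-0.37) and homologous recombination (-0.32) lie below the range and T cell markers (0.65) above it.

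The ratio also depended on the chromosome. Genes of chromosomes 9 and 20 were higher as a whole in PTIP deficient cells: the median was 0.38 (1.30-fold) over 262 genes of chromosome 9 and 0.37 (1.30-fold) over 215 genes of chromosome 20, each above all 10000 random medians, and 79.0% and 78.6% of their genes lay above 0. Genes of the Z chromosome were lower, with a median of -0.16 over 406 genes, below all random medians, and 66.7% of them below 0. The medians of the other 28 chromosomes lay between -0.06 and 0.19. Of these, 8 were outside the random range, chromosomes 6 (0.10), 22 (0.15), 24 (0.15) and 25 (0.19) above it and 1, 3, 4 and 21 below it. Chromosomes 4, 6, 21 and 24 were inside it under at least 1 alternative. Genes of chromosome 2, which carries PAXIP1, had a median of 0.01 (percentile 14.1). With the genes of chromosomes 9, 20, Z and W left out, the B cell and homologous recombination lists still stood apart on the same side.

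**Figure D3:**
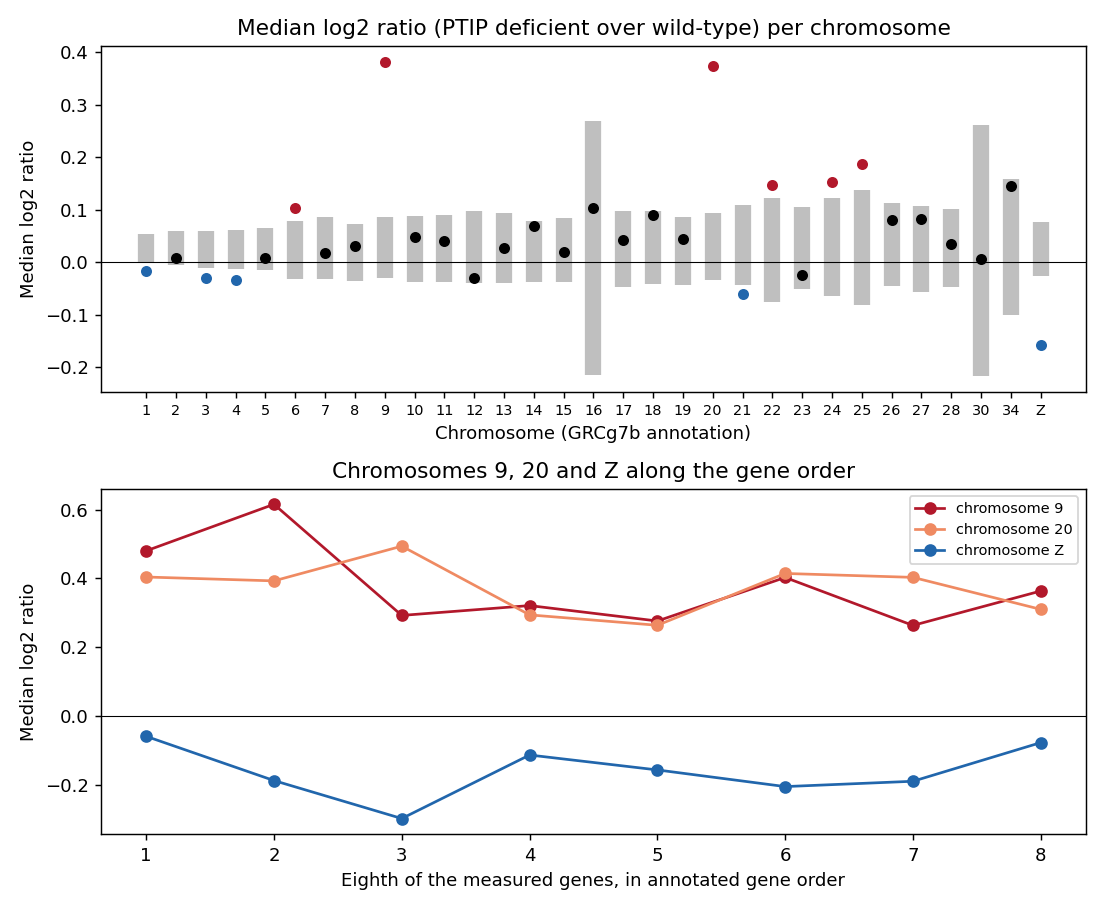
Top, median log2 ratio (PTIP deficient over wild-type) per chromosome of the GRCg7b annotation, with grey bars for the central 95% of random gene sets; bottom, medians of eighths of the measured genes of chromosomes 9, 20 and Z in gene order. All eighths of chromosomes 9 and 20 lie between 0.26 and 0.62, and all eighths of Z below 0.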

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

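Both results here were singled out after the values were seen, because they show a signal in probe sets outside the comparisons above, and no explanation was tested for either. Of 57 probe sets whose names begin with RPTR, which mark reporter and marker sequences on the array, 1 had a high signal in the PTIP deficient array: RPTR-Gga-K01193-1_at, at 2675 against 5.54 in the wild-type array. The other 56 did not exceed 101 in the PTIP deficient array, and 131.5 was the highest wild-type signal of all 57. The annotation used here does not name the sequence that this probe set detects. The 27 hybridisation control probe sets (bioB, bioC, bioD and cre), which detect transcripts added to each hybridisation, had a median log2 ratio of 0.30, with 27 of 27 higher in the PTIP deficient array, whereas the 36 labelling control probe sets (dap, lys, phe and thr) had a median of 0.08, with 26 of 36 higher.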

How the results depend on the processing

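The alternatives without chromosomes 9, 20, Z and W and with the floor at the highest reporter signal (131.5) were chosen after seeing the data. No paired analysis was possible because each genotype has 1 array, and no replicate could be left out. The PAXIP1 ratio was the same within the spread between probe sets under all 3 scalings. Without _s_at and _x_at probe sets no PAXIP1 signal reached the floor, and the log2 ratio of -1.56 came from signals of 19.7 and 6.65. The counts at least 2-fold apart, 994 higher and 952 lower, moved to 2619 and 2386 with the floor at percentile 20, 489 and 446 at percentile 60, 6165 and 5835 with no floor, 385 and 342 at the reporter floor, 2731 and 2489 at 1.5-fold and 297 and 290 at 3-fold. The SD between probe sets was 0.83, 0.35, 1.5 and 0.32 with those 4 floors, against 0.50, and the signal floor limits which differences can be read. Of 294 list percentiles under alternatives, 271 kept their call, 16 lost it and 7 gained one. With the floor at percentile 60 or at the reporter signal the T cell, macrophage, erythroid, mesenchymal, HOX and interferon lists had fewer than 5 measured members and gave no value, nor did the HOX and erythroid lists with the mean of probe sets, nor chromosome 30 and in part 16 under these and without _s_at and _x_at probe sets. At the reporter floor glycolysis lost its call at 93.8 and translesion synthesis gained one at 2.10. Without _s_at and _x_at probe sets the percentile was 7.54 for base excision, mismatch and nucleotide excision repair, 6.16 for B cell genes, 3.25 for MHC class II, 92.6 for oxidative phosphorylation and 93.2 for glycolysis, while 1.49 for translesion synthesis and 98.8 for mesenchymal and epithelial markers gained a call. Under quantile normalization ribosomal proteins lost their call at 38.5, with a median of -0.00036, glycolysis was at 87.2, proteasome at 97.9 and translesion synthesis at 2.49. With the floor at percentile 60, B cell genes were at 3.27, glycolysis at 93.2 and translesion synthesis at 0.89. Glycolysis was further at 96.0 (loess), 97.2 (floor at percentile 20), 97.0 (no floor), 93.3 (mean of probe sets) and 93.3 (unmatched random lists), and oxidative phosphorylation at 96.3 with unmatched lists. Without chromosomes 9, 20, Z and W, translesion synthesis was at 2.29. Homologous recombination, DNA replication and mitosis lists kept their call under all alternatives run, and T cell markers under those that gave them a value. Chromosomes 9, 20 and Z kept theirs too. Of the small shifts, chromosome 24 lost its call at 96.7 (quantile), 79.1 (floor at percentile 20), 86.3 (no floor) and 84.3 (without _s_at and _x_at), chromosome 4 at 2.58 (mean of probe sets) and 9.09 (without _s_at and _x_at), chromosome 21 at 3.25 (mean of probe sets) and 2.98 (reporter floor) and chromosome 6 at 96.8 (reporter floor), while chromosome 12 gained one at 0.79 (floor at percentile 60), 2.38 (without _s_at and _x_at) and 0.78 (reporter floor), 15 at 1.5 (mean of probe sets) and 18 at 97.7 (no floor) and 97.9 (reporter floor). Of 551 values of named genes, 12 were no longer 2-fold apart, 6 became so and 1 reversed: TSPAN12 was at -1.80 without _s_at and _x_at probe sets. Some of these changes rest on probe sets not measured in both arrays, among them those of TSPAN12 and PAXIP1. The means of FAN1, HSPH1 and TRIM25, which became 2-fold, took in such probe sets. So did those of BLB1, SLC16A3 and PFKM, which were no longer 2-fold. The causes were not tested, except that floors and thresholds alter how many probe sets count.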

Other observations

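All tests in this part were chosen after the result was seen, and so were the genes it names. Transcription regulators among the B cell and germinal centre lists differed in both directions or little. The log2 ratio was -4.07 for IRF4, -2.08 for POU2AF1, -1.24 for BCL6, -1.05 for SPI1, -1.03 for FOXO1, -0.94 for IKZF1 and -0.63 for EBF1, whereas it was 1.03 for STAT3 and 0.81 for TCF3, which encodes E proteins. MYC had a signal of 29115 in wild-type and 32646 in PTIP deficient cells, XBP1 16744 and 18008, and IRF8 2120 and 2046. PAX5 could not be read from these arrays, since 1 probe set gave 96.7 and 122 and another 107 and 6.97. The T cell gene CD3D was bright in both arrays, at 8831 and 15919, although CD3E had 46.5 and 45.5. Of the 11271 probe sets without a single named gene, 4363 were measured in both arrays, 233 of them at least 2-fold higher and 214 at least 2-fold lower.

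The shift of chromosomes 9 and 20 was spread over many of their genes. Of the 477 measured, 78.2% (bootstrap 95% interval 74.4 to 82.0) lay above the median of the other autosomes. The intervals in this part resample genes of the same 2 arrays as if genes were independent. They cover no spread between arrays, cultures or clones. A few strongly different genes cannot carry a median, so this share describes the shift and tests no cause of it. A bias shared by the smaller, gene-dense chromosomes could account for at most part of the shift. Over all other autosomes numbered 6 and up the median was 0.063 above that of chromosomes 1 to 5 (interval 0.047 to 0.079). Chromosome 25 was highest at 0.19, against 0.38 and 0.37 on chromosomes 9 and 20. No link to size or gene density was itself tested. The set of other autosomes replaced a narrower one, picked after the medians were seen, that left out chromosomes 6, 22, 24 and 25. All 16 eighths of the 2 chromosomes in gene order had a median above 0.15, from 0.26 to 0.62. Extra copies of both chromosomes in the PTIP deficient cells would raise all parts of them. Extra copies are a hypothesis from the same data, and the bar of 0.15 was set after the medians were seen. Every eighth already lay above that bar, so the count could not go against extra copies. The size of the shift was not compared with that of a given copy number. The base composition of the genes was not tested here. Whether such a gain would have arisen by chance in the clone or with PTIP loss is not addressed by 1 clone per genotype.

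HINTW, a gene of the W chromosome, had signals of 25415 and 1603 with its 2 probe sets in wild-type cells and 2.42 and 74.6 in PTIP deficient cells, and Z-linked genes were also lower. A sample of male cells in place of the labelled line would raise Z-linked genes, which instead lay 0.18 below the autosomes (log2 difference -0.18, interval -0.23 to -0.13). Loss of the W chromosome may account for HINTW. For 14 W-assigned probe sets the wild-type signal was at least 10 times the floor of 31.0. Only 3 of them were at least 10-fold lower, a signal under the floor being counted at the floor. These were both HINTW probe sets and that of LOC430910 (27.8 against 1971 in wild-type). The rest of the 14 belonged to HNRNPKL, NEDD4L, UBE2R2L, MBD2 and LOC426615 alone. Below that bar, SPIN1L (3.08 against 147) and LOC431003 (18.0 against 134) were lower, while other W-assigned probe sets went both ways. What keeps loss of the W open is that the rest of the 14 could detect transcripts of related Z-linked copies, which was not tested.

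Admixture of cells that express none of the B cell list would lower all its genes by a like factor. Yet 15 of 22 list genes with a wild-type signal of at least 1000 were less than 2-fold lower, while JCHAIN was at least 90.8-fold lower. This argues against such an admixture only. Cells that express part of the list would leave some genes little changed, and these values cannot speak to them. Dosage of chromosomes 9, 20, Z and W does not account for the lower B cell list, which was at percentile 0.02 without their genes. Dosage of other chromosomes or of parts of chromosomes was not tested. An effect of PTIP loss and a difference between cell clones unrelated to PTIP cannot be told apart with 1 array per genotype. T cell markers, with a median of 0.65, and the marker probe set with a signal of 2675 were higher in the same array.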
